A study of Homo sapiens with 10 samples.

How the data were processed

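RNA was measured by sequencing in 10 libraries of U2932, an established human line of diffuse large B cell lymphoma, a cancer of mature B cells. The labels give 5 clones as CREBBP+/+ and 5 as CREBBP+/-. CREBBP encodes a histone acetyltransferase that acts as a transcriptional coactivator. Per the labels' protocols, cells were grown in RPMI with heat-inactivated serum, collected by centrifugation and frozen, RNA was isolated on a column kit, and libraries were made with a TruSeq RNA kit. How the CREBBP copy was altered, how each clone was derived and whether libraries were made on different days are not given in the sources used here.

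The authors deposited raw read counts per Ensembl gene, with 1 column per library and no pooling of clones. The submitters' processing notes name FastQC, STAR, featureCounts, DESeq2 and the build GRCh38, without versions or roles. The counting options, the gene annotation and any use of strand are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical genes, could be split between them in ways that cannot be checked. The deposited counts of 10000 or more are rounded to 4 significant digits, which moves each of them by far less than the spread between clones. The table holds 21174 gene identifiers, of which 20804 (98.3%) were matched to a symbol and 370 were not, and 4999 genes had no count in any library. Coordinates are those of the GENCODE annotation of GRCh38.

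The 5 columns of CREBBP+/+ libraries carry the names of the labelled clones. The 5 columns of CREBBP+/- libraries are named Het_6 to Het_10, numbers that no labelled clone carries, so they were used as members of their group without a pairing to a labelled clone. Library names below are those of the columns. Total counts ranged from 10615977 (Het_9) to 23020694 (Het_6). Every pair of libraries differed by more than sampling noise (smallest chi-square per gene 7.77, Het_9 against Het_10, over genes with at least 20 counts in the pair; largest 130), so none was treated as the same library deposited again. This does not show that libraries came from separate cultures, and the pairs Het_9 with Het_10 and Het_6 with Het_7 (8.08) were the closest.

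The main comparison set 5 CREBBP+/- against 5 CREBBP+/+ libraries with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. It used TMM normalization, robust dispersions, no covariate and a filter on low counts (filterByExpr, minimum count 10, minimum total 15) that left 11961 genes and removed 9213. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 CPM (counts scaled to a library total of 1e+06, with TMM factors) were computed with a prior count of 2. Standard errors of log2 fold changes (CREBBP+/- over CREBBP+/+) come from the same F statistics. Single values per library were compared by an exact two-sided permutation test over the 252 assignments of 5 and 5 libraries, whose smallest possible p is 0.00794.

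A set of 21 gene lists with 380 distinct genes was fixed before the data were examined. The 20 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided), and adjusted p-values run over the 20 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. The MHC class II list was written with the knowledge that lower class II expression is described for CREBBP-mutant lymphoma, so its count is not independent evidence of its direction. The list of genes that separate subpopulations of U2932 was written from memory of the literature.

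Genes are named by a rule fixed before the data were examined: CREBBP and EP300, up to 12 genes per direction past the threshold with no overlap between groups and at least 1 CPM, all tested members of the MHC class II list, and up to 4 members with the smallest p of each other list. No gene met the rule on the threshold. Naming 4 members of lists called by camera and 2 of the rest, naming the genes called by DESeq2 and naming all 7 subpopulation genes were decided after their values were seen. Single-gene results of some list members are not reported here; these genes stayed in the list tests.

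Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper-quartile factors within edgeR, no filter, a filter of 1 CPM in 5 libraries, a log2 fold limit of 1, and leaving out each library. Added after the data were seen were the edgeR likelihood ratio test, 3 library clusters as a covariate, 2 surrogate variables (sva 3.50.0), leaving out Het_9 and Het_10 together, an exact permutation test of list means, and DESeq2 under several of these. The clusters came from average-linkage clustering of log2 CPM without CREBBP and the class II list. With the clusters as a covariate, Het_9 and Het_10 do not inform the genotype effect, since no CREBBP+/+ library shares their cluster. An adjusted p that DESeq2 left undefined (8103 genes) was kept out of all counts.

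The procedure was tested on simulated data for 5 against 5 libraries and 11961 genes, with the dispersion of each gene as estimated. The edgeR test recovered 60% of 2-fold and 88% of 4-fold changes with 6 false calls, and DESeq2 recovered 76% and 93% with 36 false calls. The simulated counts were drawn independently for each gene and library, without the library clusters seen in the data. These rates therefore need not hold for the real comparison.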

Results

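Gene expression was compared between clones of U2932, a diffuse large B cell lymphoma line, that carried CREBBP on both alleles (CREBBP+/+, 5 libraries, WT_1 to WT_5) and clones labelled CREBBP+/- (5 libraries, Het_6 to Het_10). Total counts, in units of 1e+06 (M), were 19.0 ± 1.92 M in CREBBP+/+ and 18.8 ± 4.86 M in CREBBP+/- libraries (mean ± SD, n = 5 each), with Het_9 the shallowest at 10.6 M. The comparison asked which transcripts differ when a CREBBP allele is altered. The labels do not say whether the clones were grown and prepared separately, so p-values measure the spread between these libraries.

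The libraries fell into 3 clusters that crossed the genotypes. WT_1, WT_2 and Het_8 lay together, as did WT_3, WT_4, WT_5, Het_6 and Het_7, and Het_9 and Het_10 formed a cluster without a CREBBP+/+ library. The first 3 principal components held 52.4%, 19.4% and 12.8% of the variance of log2 CPM. The cluster of 5 was not uniform. On the third component WT_3, Het_6 and Het_7 scored -25.5, -27.8 and -24.3, and WT_4 and WT_5 scored 25.2 and 40.0.

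**Figure D1:**
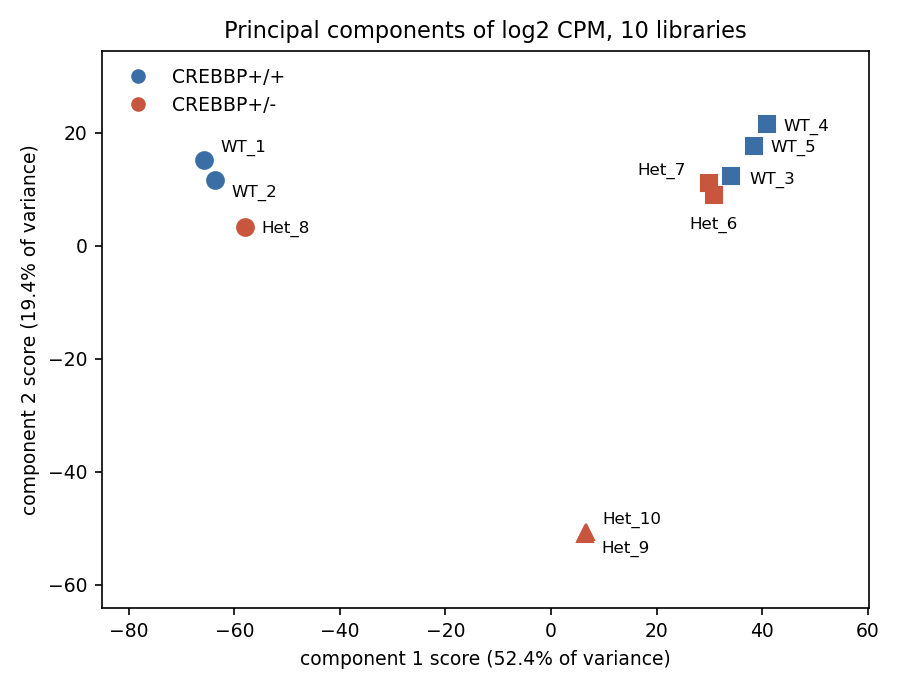
Scores of the 10 libraries on the first 2 principal components of log2 CPM (52.4% and 19.4% of variance), with color for genotype and marker shape for the 3 library clusters. WT_1, WT_2 and Het_8 sit at negative scores of the first component, and Het_9 and Het_10 at the lowest scores of the other.

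CREBBP mRNA was 1.65-fold lower in CREBBP+/- libraries. CREBBP (ENSG00000005339, chromosome 16, 3725054 to 3880713, GRCh38) averaged 115 ± 13.5 CPM in CREBBP+/+ and 69.6 ± 10.2 CPM in CREBBP+/- libraries (mean ± SD, n = 5 each), and each CREBBP+/- library lay below each CREBBP+/+ library (exact permutation p = 0.00794, the smallest these group sizes allow). The log2 fold change was -0.73 (SE 0.12, 95% confidence interval -0.99 to -0.46). EP300, the paralogous acetyltransferase (ENSG00000100393, chromosome 22, 41092592 to 41180077), had 146 ± 17.0 and 152 ± 19.1 CPM (log2 fold change 0.06, SE 0.11, exact permutation p = 0.587, n = 5 each, and 0.01 to 0.12 leaving out 1 library). Over all genes tested, CREBBP did not pass the edgeR threshold (adjusted p = 0.395), and it passed that of DESeq2 (adjusted p = 0.000107).

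**Figure D2:**
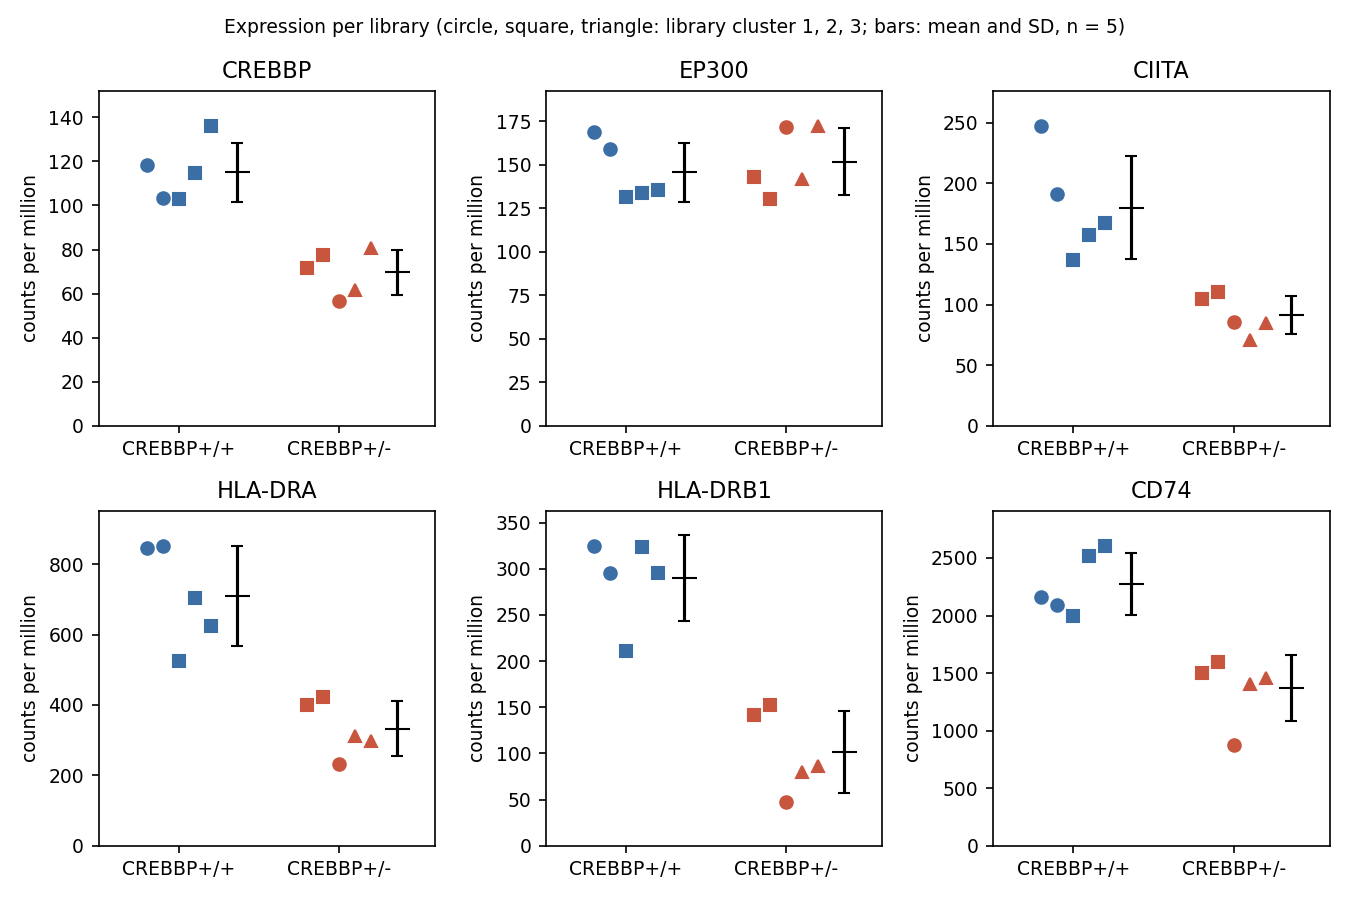
CPM of CREBBP, EP300, CIITA, HLA-DRA, HLA-DRB1 and CD74 in each library, with color for genotype, marker shape for the library clusters, and bars for mean ± SD of 5 libraries. CREBBP averaged 115 CPM in CREBBP+/+ and 69.6 CPM in CREBBP+/- libraries, and EP300 146 and 152 CPM.

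MHC class II genes, which encode the molecules that present peptides to CD4 T cells, were lower in CREBBP+/- libraries. Of 17 members tested, 13 fell when p-values were adjusted over the list alone, 0 passed the edgeR threshold over all genes tested, and 4 passed neither. CIITA, the master transactivator of class II genes (ENSG00000179583, chromosome 16, 10866222 to 10943021), averaged 180 ± 42.5 CPM in CREBBP+/+ and 91.3 ± 15.9 CPM in CREBBP+/- libraries, 1.97-fold lower. HLA-DRA, the alpha chain of HLA-DR (ENSG00000204287, chromosome 6, 32439878 to 32445046), went from 710 ± 141 to 333 ± 78.0 CPM, and CD74, the class II chaperone (ENSG00000019582, chromosome 5, 150401637 to 150412969), from 2272 ± 268 to 1367 ± 286 CPM (mean ± SD, n = 5 each).

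Among the class II genes, HLA-DPB1 (ENSG00000223865, chromosome 6, 33075990 to 33089696) had the smallest p of all genes tested, with a log2 fold change of -1.17 (SE 0.17, edgeR adjusted p = 0.355 over all genes and 0.000504 over the list alone). HLA-DRA (-1.09, SE 0.19) and CIITA (-0.98, SE 0.17) each had an edgeR adjusted p of 0.000986 over the list alone. The log2 fold changes were -1.51 for HLA-DRB1, -1.74 for HLA-DQB1, -1.78 for HLA-DRB5, -1.19 for HLA-DQA2 and -1.08 for HLA-DQA1 (SE 0.45). HLA-DQA1 had 103 and 115 CPM in Het_6 and Het_7, just below the CREBBP+/+ minimum of 116 CPM. It had 14.4 to 43.8 CPM in Het_8, Het_9 and Het_10. Reads could be misassigned between close paralogs, such as HLA-DRB1 and HLA-DRB5 or HLA-DQA1 and HLA-DQA2. HLA-DPA1 had -0.79, CD74 -0.73, HLA-DMB -0.69, HLA-DMA -0.63 and HLA-DOA -0.58. HLA-DOB (-0.21, SE 0.27) and the 3 subunits of the RFX complex that binds class II promoters, RFX5 (0.03, SE 0.09), RFXANK (0.14, SE 0.19) and RFXAP (0.29, SE 0.19), did not pass. In 12 of the 17 genes all CREBBP+/- libraries lay below all CREBBP+/+ libraries.

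As a list, the class II genes had a median log2 fold change of -0.79 and a camera adjusted p of 7.17e-18. The call was lost with an estimated correlation (adjusted p = 0.0803 with an estimated correlation) and held with fry (adjusted p = 0.0105). The mean log2 CPM of the list was 6.86 ± 0.13 in CREBBP+/+ and 6.01 ± 0.38 in CREBBP+/- libraries (n = 5 each), with no overlap (exact permutation p = 0.00794 and 0.0794 when adjusted over 20 lists). Within library clusters the difference was -1.53 for WT_1, WT_2 and Het_8 and -0.49 for the cluster of 5, while the cluster of Het_9 and Het_10 held no CREBBP+/+ library. The list was drawn up knowing that this direction is described for CREBBP-mutant lymphoma, so it is not independent evidence.

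**Figure D3:**
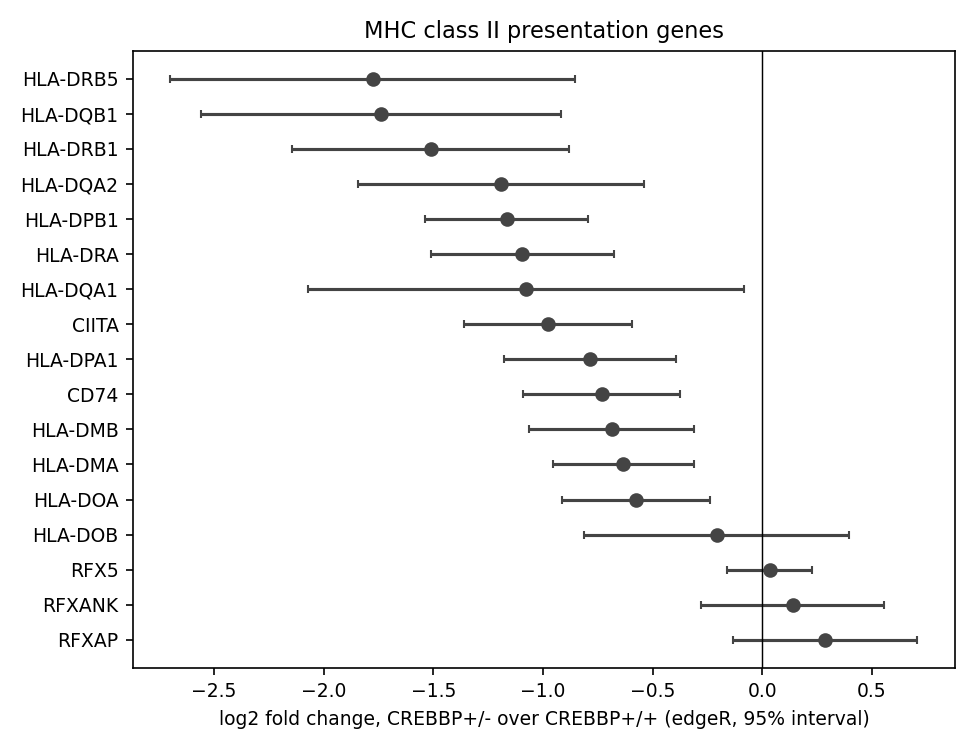
Log2 fold change (CREBBP+/- over CREBBP+/+) of the 17 MHC class II list members from edgeR, with points for estimates and bars for 95% confidence intervals. The intervals of 13 genes lie below 0, and those of HLA-DOB, RFX5, RFXANK and RFXAP include 0.

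Transcripts of the mitochondrial genome, which encodes subunits of the respiratory chain, took a larger share of the counts in CREBBP+/- libraries. The share was 8.11 ± 0.250% in CREBBP+/+ and 9.50 ± 0.476% in CREBBP+/- libraries (n = 5 each, exact permutation p = 0.00794), with ranges of 7.85 to 8.51% and 8.89 to 10.2%. All 13 mitochondrial mRNAs had a point estimate above 0 (median log2 fold change 0.25), and 2 rose when adjusted over the list alone, MT-ATP8 (0.34, SE 0.09) and MT-ND4L (0.32, SE 0.10), each with an edgeR adjusted p of 0.0453. MT-ATP6 (0.25, SE 0.08) and MT-ND2 (0.33, SE 0.12) did not pass. MT-ATP8 overlaps MT-ATP6, and MT-ND4L overlaps MT-ND4, so their counts are uncertain. The camera adjusted p of the list was 5.56e-09, lost with an estimated correlation (adjusted p = 0.0803 with an estimated correlation) and held with fry (adjusted p = 0.0105). Within clusters the share was higher by 1.80 percentage points in Het_8 than in WT_1 and WT_2, and by 1.29 points in Het_6 and Het_7 than in WT_3, WT_4 and WT_5.

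**Figure D4:**
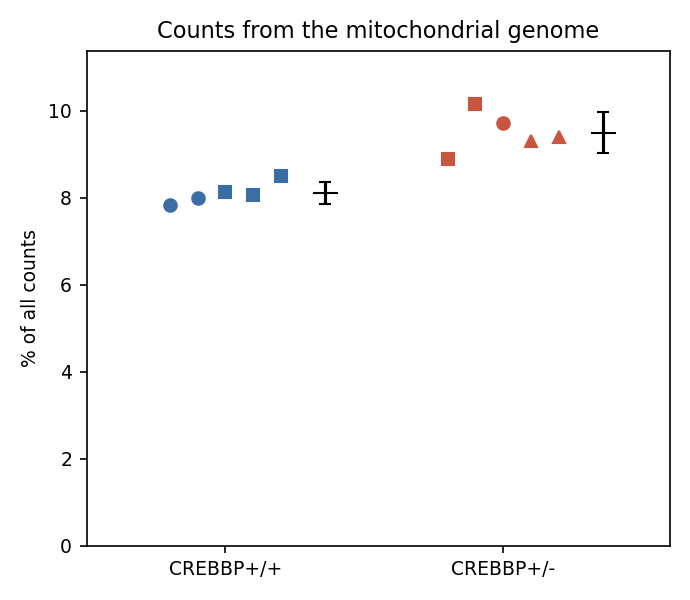
Percent of all counts that came from the mitochondrial genome in each library, with color for genotype, marker shape for the library clusters and bars for mean ± SD of 5 libraries. CREBBP+/+ libraries lie between 7.85 and 8.51% and CREBBP+/- libraries between 8.89 and 10.2%.

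Camera also called 4 lists lower in CREBBP+/- libraries, without any member past the edgeR threshold over all genes or over the list alone. Of 25 cell cycle genes, 22 had a point estimate below 0 (median -0.12, camera adjusted p = 0.000937, and adjusted p = 0.304 with an estimated correlation). Among them were the mitotic genes AURKB (-0.30, SE 0.11), CDC20 (-0.33, SE 0.16), BUB1 (-0.23, SE 0.11) and CENPA (-0.27, SE 0.14). Of 21 B cell receptor signalling genes, 18 were below 0 (median -0.23, camera adjusted p = 0.00313, and adjusted p = 0.304 with an estimated correlation), with the phosphatase INPP5D at -0.49 (SE 0.17), the adaptor BLNK at -0.25 (SE 0.10) and the kinase BTK at -0.31 (SE 0.15). Of 18 MHC class I presentation genes, 16 were below 0 (median -0.14, camera adjusted p = 0.00407, and adjusted p = 0.442 with an estimated correlation), with HLA-E at -0.46 (SE 0.21), PSMB10 at -0.32 (SE 0.14), TAP1 at -0.15 (SE 0.07) and HLA-F at -0.35 (SE 0.21). All 12 tested immunoglobulin constant regions were below 0 (median -0.50, camera adjusted p = 0.0111, and adjusted p = 0.502 with an estimated correlation), with IGHA2 at -1.09 (SE 0.56), IGHA1 at -1.08 (SE 0.58), IGHG3 at -0.35 (SE 0.27) and IGHG2 at -0.74 (SE 0.71), near-identical genes whose reads could be split. Leaving out 1 library gave -0.58 to -0.19 for IGHG3 and -1.38 to -0.44 for IGHG2.

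These 4 calls were also lost with fry, with an adjusted p of 0.263 for cell cycle, 0.263 for B cell receptor signalling, 0.407 for class I and 0.407 for immunoglobulin genes. Without Het_8 the camera adjusted p was 0.0965, 0.117, 0.226 and 0.0830 in the same order. Without WT_5 it was 0.0527 for B cell receptor signalling, and the immunoglobulin call was also lost without WT_3, WT_4, WT_5, Het_9 or Het_10 (0.0507 to 0.104). The immunoglobulin list moved with the library clusters: its mean log2 CPM was 4.39 and 4.56 in Het_9 and Het_10, 4.87 to 5.09 in WT_1, WT_2 and Het_8, and 5.71 to 6.32 elsewhere. In fits added after the data were seen, its camera adjusted p was 0.713 without Het_9 and Het_10 and 0.296 with the clusters as a covariate.

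The other 14 lists were not called by camera. Plasma cell genes had a median of -0.24 (adjusted p = 0.0717), with SSR4 at -0.26 (SE 0.09) and MZB1 at -0.61 (SE 0.27). Stress and immediate early genes had a median of 0.19 (adjusted p = 0.0717), with JUN at 2.01 (SE 0.62) and FOS at 0.68 (SE 0.35), and JUN stood at 17.2 to 18.7 CPM in Het_8, Het_9 and Het_10 against 1.54 to 4.34 CPM in the other 7 libraries. Cholesterol synthesis genes had a median of 0.09 (adjusted p = 0.109), with MSMO1 at 0.54 (SE 0.23, and 0.32 to 0.66 leaving out 1 library) and IDI1 at 0.27 (SE 0.14, and 0.14 to 0.33). Both were highest in Het_9 and Het_10, with 35.2 and 26.3 CPM of MSMO1 against 13.7 to 19.3 CPM in the other 8 libraries, and 209 and 176 CPM of IDI1 against 119 to 141 CPM. Acetyltransferases, deacetylases and corepressors had a median of -0.02 (adjusted p = 0.182), with CREBBP the member past the threshold over the list alone. MYC targets had a median of -0.08 (adjusted p = 0.320), with BOP1 at -0.40 (SE 0.12) and GNL3 at 0.20 (SE 0.07). Medians were -0.02 for glycolysis (adjusted p = 0.420; GAPDH -0.24, PFKL -0.40), -0.06 for B cell surface molecules (0.420; CD274 0.65), -0.21 for cytokines and adhesion (0.509; IL2RG -0.49, CXCR5 0.50), -0.02 for NF-kappaB targets (0.743; CCL4 -0.87, CFLAR 0.17) and -0.0025 for other chromatin regulators (0.747; KDM6A 0.11, ARID1A -0.15).

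For 4 of these lists the median, the mean and the camera direction differed in sign. Germinal centre B cell genes had a median log2 fold change of 0.15, a mean of -0.02 and a camera direction above 0 (adjusted p = 0.520), with TCL1A at -0.55 (SE 0.43). Interferon response genes had a median of -0.02 and a mean of 0.02 (direction below 0, adjusted p = 0.640), with STAT2 at -0.28 (SE 0.09) and OAS2 at -0.60 (SE 0.27, and -0.72 to -0.31 leaving out 1 library). Targets of p53 had a median of 0.01 and a mean of -0.03 (direction below 0, adjusted p = 0.640), with BAX at -0.31 (SE 0.12) and BBC3 at -0.45 (SE 0.21, and -0.54 to -0.24 leaving out 1 library). Genes reported to separate subpopulations of U2932 had a median of 0.05 and a mean of -0.06 (direction above 0, adjusted p = 0.642), with BCL6 at 0.26 (SE 0.31) and MS4A1 at 0.19 (SE 0.25). For cytokines and adhesion genes the mean log2 CPM was higher by 0.02 in CREBBP+/- libraries although the median fold change was below 0.

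Leaving out 1 library brought 4 of the uncalled lists past the camera threshold. The adjusted p was 0.0140 for plasma cell genes without WT_4 and 0.0427 without Het_10, 0.0242 for MYC targets without WT_4, and 0.0159 for cholesterol synthesis without WT_1 and 0.0239 without Het_6. For stress genes it was 0.0237 without WT_1, 0.0293 without Het_6 and 0.0156 without Het_7. Among single genes, leaving out 1 library also moved the log2 fold change of HLA-E (-0.56 to -0.30), BTK (-0.40 to -0.21), TCL1A (-0.92 to -0.28), ARID1A (-0.23 to -0.09), BCL6 (0.10 to 0.40) and MS4A1 (0.06 to 0.33) by more than 1.5-fold. The same held for HLA-DOB (-0.36 to -0.03), RFX5 (0.01 to 0.08), RFXANK (0.04 to 0.25) and RFXAP (0.17 to 0.38).

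Of 24 markers of T, NK, myeloid, erythroid, stromal and epithelial cells, 22 had too few counts to be tested. EPCAM (14.7 ± 11.4 and 21.9 ± 4.86 CPM, n = 5 each) and CD14 (0.711 ± 0.303 and 0.789 ± 0.131 CPM, n = 5 each) were tested and did not pass in edgeR (adjusted p = 0.988 each). NCAM1 had 43 and 56 counts in Het_9 and Het_10 and at most 4 elsewhere, and DCN had 14 and 19 counts there and 0 elsewhere; both genes were chosen after their values were seen.

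Across all genes, edgeR called 0 of 11961 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 596 genes (285 higher and 311 lower in CREBBP+/-), where chance gives 598, but leaving out 1 library gave 327 to 1124. Limma-voom also called 0. DESeq2 called 34 genes, 14 higher and 20 lower. Of the 20 lower genes, 12 were CREBBP, 10 class II list members and HLA-DQB2 (log2 fold change -2.13, SE 0.39, DESeq2 adjusted p = 0.000107), a paralog of HLA-DQB1. The 10 class II calls became 5 without Het_9 and 6 without WT_1, WT_4 or Het_10, and 4 without Het_9 and Het_10 together, a fit added after the data were seen. The groups did not overlap in 122 of the 11961 genes (1.02%, where chance gives 0.794%).

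The other genes called by DESeq2 were chosen after their values were seen. Lower in CREBBP+/- libraries were RARA, a retinoic acid receptor (39.6 ± 2.31 and 28.1 ± 2.38 CPM, log2 fold change -0.49), RAC2, a hematopoietic GTPase (185 ± 21.2 and 123 ± 12.7 CPM, -0.58), KCNAB2 (-0.67), the replication licensing factor CDT1 (-0.39), ERGIC1 (-0.44), SLC15A4 (-0.39), ACP5 (-2.55) and CYC1, a nuclear-encoded subunit of respiratory complex III (-0.27). Higher were the mitochondrial MT-ATP6 and MT-ATP8, the chaperone HSPA4L (25 ± 2.37 and 37.8 ± 5.31 CPM, 0.59), ZNF493 (0.46), EXD2 (0.51), SPINT1 (1.47) and ELOVL7 (2.03). Levels in CREBBP+/+ and CREBBP+/- libraries were low for ACP5 (1.20 and 0.206 CPM), SPINT1 (1.75 and 4.88 CPM) and ELOVL7 (0.636 and 2.61 CPM). ENAH, an actin regulator, averaged 0.452 ± 0.151 and 12.8 ± 12.6 CPM, with 23.3 and 27.9 CPM in Het_9 and Het_10, 11.4 in Het_8 and 0.598 and 0.675 in Het_6 and Het_7. MAP2, SCD5, PLEKHA7, HOXA7 and MVB12B averaged 0.267 to 1.10 CPM in CREBBP+/+ and 4.36 to 12.5 CPM in CREBBP+/- libraries, each with its highest values in Het_9 and Het_10. HOXA7 had 11.2 and 8.29 CPM there, against 0.555 in Het_6 and 0.048 in Het_7, within or below the CREBBP+/+ range of 0.104 to 0.655. MVB12B had 9.28 and 9.97 CPM there, and 0.579 in Het_7 against 1.26 in WT_3. PHLDB2 (0.154 and 1.46 CPM) was below the edgeR filter.

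The DESeq2 count fell to 15 without WT_1, 18 without WT_4, 12 without Het_9 and 16 without Het_10, and rose to 112 without WT_3 and 122 without Het_8, with CREBBP called each time. In fits added after the data were seen it was 12 without Het_9 and Het_10 together and 195 with the clusters as a covariate. In the latter fit the genotype effect rests on Het_6, Het_7 and Het_8 against the CREBBP+/+ libraries. Without Het_6, edgeR called 1 gene, lower in CREBBP+/- libraries.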

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

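The test of the subpopulation genes and the comparison of the Het_8 values with WT_1 and WT_2 were chosen after the library clusters had been seen. A library was singled out when its gap to the nearest of the other 4 in its group was a large part of the group's range. This was so for 17 of 224 groups of values, where chance gives about 1 in 20 (11), and 13 of the 17 concerned Het_8, the single CREBBP+/- library in the cluster of WT_1 and WT_2.

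Het_8 stood below the other CREBBP+/- libraries in log2 CPM of CD74 (9.77, next 10.46), HLA-DOA (5.18), RFXANK (4.95), PSMB10 (4.94), CXCR5 (8.20), IGHA2 (1.84), EPCAM (3.78), HSPA4L (4.85) and CD38 (6.59). It stood above them in TCL1A (9.31, next 8.15). Its mean log2 CPM was lowest for the MHC class I list (6.43), the germinal centre list (5.85) and the interferon list (2.80). WT_3 was the lowest CREBBP+/+ library for HLA-DRB1 (7.72) and for the mean of the class II list (6.64). Het_10 was the lowest CREBBP+/- library for KCNAB2 (5.67) and the highest for CYC1 (7.26).

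For 8 of the 13 Het_8 values, WT_1, WT_2 and Het_8 all lay on the same side of the other 7 libraries, as they did for 33.2% of all genes tested. These were TCL1A (log2 CPM 9.31 to 9.69, against 7.76 to 8.29), CXCR5, IGHA2, RFXANK, EPCAM, CD38, the germinal centre list (5.55 to 5.85, against 6.55 to 6.76) and the interferon list (2.80 to 3.09, against 3.38 to 3.61), so these values went with the cluster. The other 5 did not: CD74, HLA-DOA, PSMB10, HSPA4L and the class I list. WT_1 and WT_2 had the highest HLA-DOA of the 10 libraries (89.2 and 81.0 CPM, against 36.2 in Het_8). The 7 genes reported to mark subpopulations of U2932 were compared between the clusters. WT_1, WT_2 and Het_8 had the lowest log2 CPM of the plasma cell regulator PRDM1 (0.92, 1.93 and 1.26, against 3.23 to 6.06) and of BCL6 (7.91 to 8.32, against 9.04 to 9.38), and the highest of MYC (7.01 to 7.14, against 4.74 to 5.71) and BCL2 (10.23 to 10.40, against 8.88 to 10). MS4A1 (9.45 to 9.66) and CD38 (5.93 to 6.59) were lowest there, and IRF4 ranged from 8.53 to 9.50 over the 10 libraries.

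A difference in depth is argued against, since all 10 libraries kept their cluster after thinning to the smallest total. The mean absolute loading of the 7 genes on the first component lay at percentile 100 of 10000 matched random lists, which is in line with clones grown from different subpopulations of the line. Expression of each gene was set against its median over libraries. In 10 of 10 libraries the largest absolute median over 20 Mb windows exceeded 95% of 200 shufflings. Chromosome 5 at 0 to 20 Mb had -0.84 in Het_9 and -0.78 in Het_10. Windows from 60 to 140 Mb of chromosome 10 had 0.357 to 0.505 in WT_1, WT_2 and Het_8 and -0.235 to -0.002 in the others. Not every window followed the clusters. Chromosome 9 at 80 to 100 Mb had -0.456 in WT_1 but -0.072 in WT_2 and 0.025 in Het_8. Gains or losses of segments may thus contribute, although neighbouring genes can also share regulation. Subpopulations of the line and changes of segments both stay open, and neither was tested against DNA. Genotype does not separate the clusters, since 2 of the 3 hold both.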

How the results depend on the processing

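Chosen after the data were seen were the edgeR likelihood ratio test, the cluster covariate, the surrogate variables, the fits without Het_9 and Het_10 together, the permutation test of list means and all DESeq2 settings beyond its plain fit. No paired analysis was possible because the CREBBP+/- columns carry numbers that no labelled clone has; the planned block on replicate number was not run. Where a cause is not named, the cause was not tested. The largest limit of depth is Het_9, with 10615977 counts.

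Genes called by edgeR stayed at 0 with other size factors, filters, voom, clusters, surrogate variables and without Het_9 and Het_10. The fold limit could not change this count, since it only removes genes from those called in the main fit. The count was 34 with DESeq2 (14 higher, 20 lower) and 16 with the likelihood ratio test (3 higher, 13 lower, among them CREBBP with an adjusted p of 0.00108 and 8 class II list members), and leaving out 1 library gave 0 to 1 genes, in total and lower. The DESeq2 count was 195 with clusters as a covariate (26 shared with the 34), 12 without Het_9 and Het_10 (10 shared), and 12 to 122 leaving out 1 library. CREBBP ran from -0.66 to -0.78 leaving out 1 library and passed the threshold with DESeq2 and the likelihood ratio test (-0.72 each). The class II count over the list alone was 12 to 13 under all settings tried. Many named genes were chosen for a small p in these data, and the settings share most libraries. Kept direction is therefore partly built in. Of 84 named genes, direction was kept in 1422 of 1428 gene settings. The exceptions, all close to 0, were RFXANK (-0.0078), RFX5 (-0.046) and CD14 (-0.023) with clusters, RFX5 (-0.033) and IGHG3 (0.016) without Het_9 and Het_10, and CD14 leaving out 1 library (-0.043 to 0.345).

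Adjusted p-values of lists called by camera were as follows with an estimated correlation, fry and the exact permutation test of list means. Class II had 0.0803, 0.0105 and 0.0794, and mitochondrial mRNAs had the same 3 values. The 0.0794 says little, since both lists already had the smallest unadjusted p these group sizes allow (0.00794). Class I had 0.442, 0.407 and 0.556, B cell receptor signalling 0.304, 0.263 and 0.619, cell cycle 0.304, 0.263 and 0.317, and immunoglobulins 0.502, 0.407 and 0.619. Immunoglobulins had 0.296 with clusters and 0.713 without Het_9 and Het_10. Leaving out 1 library gave 1.07e-20 to 6.78e-12 for class II, 8.98e-11 to 5.89e-06 for mitochondrial mRNAs, 0.000543 to 0.226 for class I, 0.000270 to 0.117 for B cell receptor signalling, 0.000159 to 0.0965 for cell cycle and 0.000391 to 0.104 for immunoglobulins.

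Of the lists not called, plasma cell genes passed without a filter (0.0419), with clusters (0.0358) and with surrogate variables (0.0108). The camera direction turned with clusters for germinal centre genes (0.859), and for NF-kappaB targets, MYC targets, chromatin regulators, glycolysis and cholesterol synthesis (0.754 each). It turned without Het_9 and Het_10 for NF-kappaB targets and chromatin regulators (0.759 each), glycolysis (0.693), cholesterol synthesis (0.713) and stress genes (0.988), without a filter for interferon genes (0.571), and in list means for interferon genes (0.952) and cytokines (0.960). Leaving out 1 library gave 0.0140 to 0.162 for plasma cell genes, 0.403 to 0.978 for NF-kappaB targets, 0.423 to 0.872 for interferon genes, 0.0242 to 0.957 for MYC targets, 0.423 to 0.957 for chromatin regulators, 0.0159 to 0.468 for cholesterol synthesis and 0.0156 to 0.318 for stress genes. Direction turned for NF-kappaB targets without WT_4 or Het_8, interferon genes without WT_3, WT_5 or Het_8, MYC targets without WT_1 or WT_2, and chromatin regulators without Het_9.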

Other observations

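The tests of cluster share for the class II and mitochondrial patterns and the count of splits for edgeR were chosen after the results were seen. Nuclear genes of the respiratory chain did not follow the mitochondrial mRNAs: of 74 nuclear-encoded subunits tested, 55 had a point estimate below 0 and 19 above 0, with 2 lower and 0 higher at an unadjusted edgeR p under 0.05. CYC1 of complex III was among the lower genes called by DESeq2 (166 ± 7.49 CPM in CREBBP+/+ and 138 ± 8.63 CPM in CREBBP+/- libraries, n = 5 each).

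Lower class II expression was weighed against 3 technical or structural explanations. Loss of a 16p segment holding both CREBBP and CIITA, shared by all CREBBP+/- libraries, is argued against by the 31 genes between them. Their median log2 fold change was -0.16 (95% bootstrap interval over genes -0.23 to -0.094), although a smaller shift remains there. The window at 0 to 20 Mb of chromosome 16 had medians of -0.227 and -0.241 in Het_6 and Het_7. It had 0.1, 0.006 and 0.086 in Het_8, Het_9 and Het_10, and -0.087 to 0.193 in CREBBP+/+ libraries. Loss of DNA across the MHC region, shared in the same way, is argued against by 117 other genes at 29 to 34 Mb of chromosome 6 (median -0.095, interval -0.12 to -0.063). None of these starts between NOTCH4 (32194843) and ENSG00000250264 (32813767), the stretch that holds HLA-DRA, HLA-DRB1, HLA-DRB5 and the HLA-DQ genes. A loss confined to that stretch would not move the median, so it stays open. Both intervals leave out the spread between libraries, and a change in only some libraries is diluted in these medians. For unequal cluster membership, the smallest within-cluster difference was -0.49, beside -0.85 over all libraries. The list thus stayed lower within the clusters that hold both genotypes, but how much of the fall membership explains cannot be decided. The cluster of WT_1 and WT_2 holds only Het_8 as a CREBBP+/- library, and Het_9 and Het_10 have no CREBBP+/+ library beside them. WT_3, which lay near Het_6 and Het_7 on the third component, had a list mean of 6.64, against 6.29 and 6.36 in these libraries. Reads shared between HLA paralogs stay open for HLA-DRB1, HLA-DRB5 and the HLA-DQ genes and do not bear on CIITA or CD74. Differences in RNA quality or in handling between the clones stay open for class II too, since the mitochondrial share set the same libraries apart. The share of counts in the 10 largest genes also differed, with 8.30 ± 0.401% in CREBBP+/+ and 9.17 ± 0.647% in CREBBP+/- libraries (n = 5 each, exact permutation p = 0.0397). Mitochondrial mRNAs by themselves took 7.63% and 8.93% of counts, so this difference may restate the mitochondrial one.

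The larger mitochondrial share was weighed against cluster membership. For the clusters that hold both genotypes, membership is argued against by a smallest within-cluster difference of 1.29 percentage points, beside 1.39 over all libraries. Het_9 and Het_10 had no CREBBP+/+ library in their cluster to compare with. More expression of the respiratory chain altogether is argued against by its nuclear genes (median -0.078, bootstrap interval over genes -0.097 to -0.042). The median over all genes tested was -0.011. This interval too leaves out the spread between libraries. Differences in RNA quality or in handling between the clones stay open, since the labels give neither.

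Other splits of the 10 libraries into 5 and 5 were drawn 100 times out of 126, the real one included. For class II, the real split alone gave so small a camera p, 1 of 100 (real -log10 p 18.4, highest other 12.8). For mitochondrial mRNAs it was 2 of 100 (9.26, highest other 10.1, from a split of mixed genotypes with WT_1 to WT_4 and Het_9 on 1 side). Few splits thus reached so small a p for either list taken by itself. Splits treat the libraries as exchangeable, which close pairs such as Het_9 with Het_10 may not be, so chance is not excluded. Over the 20 lists, the exact permutation test of list means gave an adjusted p of 0.0794 for both. That value decides little, since both lists already had the smallest p these group sizes allow (0.00794). More splits did so for the other lists called by camera, so chance could not be excluded there either. These were cell cycle (5 of 100, real 3.85, highest other 4.75) and B cell receptor signalling (10 of 100, real 3.20, highest other 5.31). The same held for MHC class I (14 of 100, real 2.99, highest other 5.69) and immunoglobulins (19 of 100, real 2.48, highest other 6.19). With DESeq2, 23 of 100 splits called at least 34 genes (highest other 3923), so chance could not be excluded. For edgeR the count of splits decides nothing, since the real count was 0 and all 100 splits reach it by construction (highest other 2856). The split with 2856 genes set WT_1, WT_2, Het_8, Het_9 and Het_10 against the rest, which follows the library clusters and points to a structure of the samples other than genotype.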
